A study of Arabidopsis thaliana with 4 samples.

How the data were processed

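Total RNA of Arabidopsis thaliana (ecotype label ws-2) had been labelled with biotin and hybridised to 4 one-colour oligonucleotide arrays. Per the labels, 2 arrays held tumours that Agrobacterium tumefaciens had caused at the stalk base, and 2 held inflorescence stalk wounded at its base with a needle. All plants had 8 hours of light per day at 22 °C, with nights at 18 °C. The labels do not say whether the 2 arrays of a group came from separate plants. If they did not, the p-values measure technical spread only.

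The authors deposited 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes it was made with MAS5; its version, its probe definitions and any filter are not given in the sources used here. The 2% trimmed mean of the deposited values was 100 on every array, so the arrays had already been scaled to a common level. Scaling of this kind sets the average signal equal and so hides any change in the total amount of mRNA. Zeros are the lower end of the background-corrected signal and carry no order. Detection calls were not used here.

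The table held 22810 probe sets, 64 of them control probe sets, which were left out of the tests. Of the other 22746, the platform annotation used here gave 1 gene for 13513, several for 503 and none for 8730. The last 2 kinds were tested but are unnamed here. Symbols were updated through gene identifiers to the RefSeq annotation of assembly TAIR10.1, which matched 13436 of the 13513. No coordinates are printed, because the build behind the probe definitions is not given in the sources used here.

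Signals were put on a log2 scale after adding a pseudocount of 9, the rounded 20th percentile of all values. Fold changes on this scale understate the change of dim probe sets. Probe sets with a mean log2 value at or above the 40th percentile were tested, 13648 in all. The test was limma (version 3.58.1, R 4.3.3), two-sided, with group as the only term and an intensity trend in the variance prior. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 3.32. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.33, so the calls rest on the spread that limma shares across probe sets.

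Before the data were examined, 25 gene lists with 500 entries, the test, the alternatives and the rule for naming genes were fixed. The rule named the 10 largest increases and 10 largest decreases among called probe sets of 1 gene with both tumour arrays on the same side of both stalk arrays. It also named up to 3 risen and 3 fallen called members per list, and the first 2 members of each list whatever their result. Each gene was represented by its brightest probe set with 1 gene. Lists with at least 5 tested members were tested with camera (limma), two-sided, with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and the directional test fry were run beside it. Camera compares a list with the other probe sets, and fry asks whether its genes move, on balance, one way.

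The annotation gave a single-gene probe set for only 59 of the 500 entries, so 3 of the 25 lists could be tested. A further 31 families were then drawn mostly from the gene names the annotation held, after that coverage was known and before any tumour value was set against a stalk value. They have 762 entries, 667 of them with a named probe set, and 29 of these lists could be tested. Members of these lists named below are among those that the same rule gives, but which of them to print was chosen after their values were seen. They are called added lists below and were adjusted as a family of their own. The result of 1 added list is not reported here. For the closing section, 3 more lists were recalled from general knowledge after the 40 largest changes in each direction and the results of the other lists had been seen. They were also tested without the members seen there.

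The procedure was tested on simulated arrays of the tumour and stalk comparison with 200 changed probe sets among 13648 tested. Of 73 probe sets changed by 1 on the log2 scale, limma recovered 0, of 76 changed by 2 it recovered 52, and of 51 changed by 4 it recovered 49. Of 13419 unchanged probe sets, 2 were called. Far fewer probe sets were changed in the simulation than were called in the data (30.5% of those tested). The Benjamini-Hochberg cutoff was therefore stricter in the simulation, and the shares recovered do not carry over to the data. A simulated list raised by 1 passed camera (adjusted p = 4.22e-34). It did not pass with an estimated correlation (adjusted p = 0.534) or in fry (adjusted p = 0.107). None of 40 unchanged lists passed in any of these tests (0 lists each). Simulated probe sets varied independently of each other, so these lists could not test camera where the genes of a list vary together.

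The alternatives were other pseudocounts, other filters, quantile normalization, equal medians, other variance priors, the replicate number as a block, leaving out each array in turn, other thresholds and, for the counts of probe sets, 1 probe set per gene. The number of arrays limits the precision of every value.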

Results

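The series compared 2 arrays of Agrobacterium-induced tumour with 2 arrays of needle-wounded inflorescence stalk, which asks how the transcripts of tumour tissue differ from those of the organ it grew on. Signals under the pseudocount made up 18.7% and 20% of the values on the tumour arrays and 22.2% and 19.9% on the stalk arrays. Over the tested probe sets, log2 signals correlated across genes with r = 0.926 between the tumour arrays and r = 0.956 between the stalk arrays. Across tissues, r was 0.678 and 0.665 for tumour replicate 1 and 0.59 with either stalk array for tumour replicate 2. Genes are not independent replicates, so these r values describe the arrays only. The ratio of the 3′ to the 5′ control probe set for GAPDH was 0.953 and 1.27 in tumour and 1.58 and 1.4 in stalk. For actin it was 7.22 and 5.43 in tumour and 7.62 and 6.09 in stalk, and for ubiquitin 2.15 and 2.24 against 2.07 and 2.34. A second actin pair read closer together, with 2323.8 (3′) and 1499 (5′) on tumour replicate 1 and 2799.1 and 1626.1 on wounded stalk replicate 1. In a second GAPDH pair the 3′ signal lay slightly below the 5′ signal on both stalk arrays and slightly above it on both tumour arrays. These ratios therefore depend on the control pair.

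Tumour and stalk differed in a large part of the transcripts measured. Of 13648 tested probe sets, 2150 were higher and 2009 lower in tumour at an adjusted p under 0.05 (limma), which is 30.5% of those tested. At least an 8-fold change was seen for 190 of the higher and 209 of the lower probe sets. Both tumour arrays lay on the same side of both stalk arrays for 71.4% of all tested probe sets, where chance gives 33.3%. They did so for all 4159 called probe sets, which a call with 2 arrays per group nearly requires. The counts fell to 699 higher and 703 lower without wounded stalk replicate 1 and to 652 and 659 without wounded stalk replicate 2. Without tumour replicate 2, 1242 were higher and 1373 lower. In each of these fits the lone array of a group is assumed to vary like the other group.

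Among the largest increases was that of GH3.3 (AT2G23170), which conjugates auxin to amino acids. Its signal was 1364 ± 1240 in tumour and 1.5 ± 0.283 in stalk (mean ± SD, n = 2 each), a log2 change of 6.65 ± 0.69 (SE; adjusted p = 0.00391). Its tumour signals were 487.5 and 2241, and the stalk signals lay below the pseudocount. Its size and rank therefore depend on both: GH3.3 came first with the pseudocount of 9, but had 5.78 with 2 times the pseudocount and 5.56 without tumour replicate 2, where PYK10 had 6.13 and 6.54. PYK10 (AT3G09260), a beta-glucosidase known as an abundant root protein, read 2380 ± 60.8 in tumour and 16.2 ± 1.2 in stalk, a change of 6.57 ± 0.17 (adjusted p = 0.00106). PR-1-LIKE (AT2G19990), which resembles the pathogenesis-related protein PR-1, rose by 5.46 ± 0.24, and 2 class III peroxidases, AT4G36430 and Prx37 (AT4G08770), rose by 6.09 ± 0.22 and 5.33 ± 0.32. The other genes among the 10 largest increases were AT2G19970 (6.53), AT4G10270 (5.51), AT4G33560 (5.50), AT5G10040 (5.36) and AT3G20370 (5.05). Both stalk signals of AT4G33560, AT5G10040 and AT3G20370 also lay below the pseudocount. AT5G10040 had 4.52 with 2 times the pseudocount and 7.96 with none. AT2G19970, PR-1-LIKE and Prx37 each had a stalk signal below it, and AT2G19970 had 5.83 with 2 times the pseudocount and 8.43 with none. Adjusted p lay between 0.00106 and 0.00391 for all 10.

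Among the largest decreases was that of BCAT4 (AT3G19710), an aminotransferase that starts the lengthening of the methionine side chain for glucosinolates. Its signal was 13.6 ± 1.56 in tumour and 2236 ± 853 in stalk (mean ± SD, n = 2 each), a log2 change of -6.58 ± 0.30 (SE; adjusted p = 0.00106). AT1G09310 fell by 6.16 ± 0.18, from 2605 ± 358 in stalk to 27.4 ± 1.91 in tumour. AT3G21670, a nitrate transporter of the NRT1 family, fell by 5.94 ± 0.28. Changes were -5.59 ± 0.35 for the glutathione transferase GSTU20 (AT1G78370), -5.05 ± 0.23 for the cytochrome P450 CYP71B26 (AT3G26290) and -4.98 ± 0.52 for the plant defensin PDF1.2b (AT2G26020). The tumour signals of GSTU20, AT1G64360 and AT3G28270 lay below the pseudocount, so the size of their changes depends on it. GSTU20 had -4.88 with 2 times the pseudocount and -7.37 with none. AT3G21670, AT1G67870 and CYP71B26 each had a tumour signal below it, and CYP71B26 had -4.41 with 2 times the pseudocount and -6.35 with none. The others were AT1G67870, AT1G64360, AT3G28270 and AT1G67865, with changes of -5.82, -5.57, -5.41 and -5.38. Adjusted p lay between 0.00106 and 0.00396. All 20 of these genes stayed past the threshold under every alternative that tested them.

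**Figure D1:**
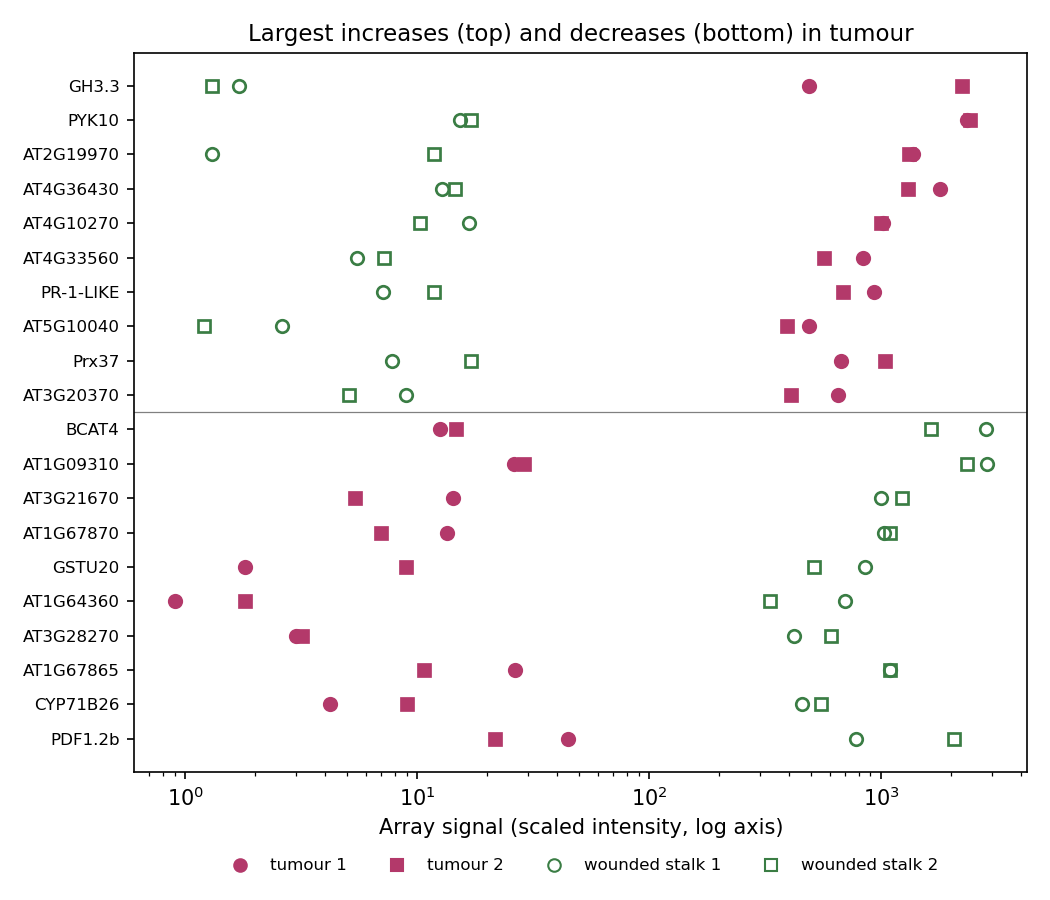
Signal of the 10 largest increases and 10 largest decreases on each array, on a log axis (scaled intensity, filled for tumour, open for wounded stalk). GH3.3 spans 487.5 to 2241 between the tumour arrays, and BCAT4 reads 12.5 and 14.7 in tumour against 2839.5 and 1633.2 in stalk.

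Genes of photosynthesis were lower in tumour. In the fixed list of light harvesting and photosystems, 5 of 7 tested members fell and 0 rose. PSAN (AT5G64040) and PSAE-1 (AT4G28750), subunits of photosystem I, had log2 changes of -1.80 ± 0.28 and -1.73 ± 0.30, and ATPC1 (AT4G04640), a chloroplast ATP synthase subunit, one of -1.45 ± 0.29 (SE; adjusted p = 0.0103, 0.0131 and 0.0182). In the list of the Calvin cycle and photorespiration, 4 of 5 fell. RCA (AT2G39730), rubisco activase, dropped from 3377 ± 144 in stalk to 458 ± 168 in tumour, a change of -2.91 ± 0.27 (adjusted p = 0.00332). Changes were -3.69 ± 0.57 for hydroxypyruvate reductase (HPR, AT1G68010), -2.92 ± 0.32 for SBPASE (AT3G55800) and -2.32 ± 0.39 for phosphoribulokinase (PRK, AT1G32060). Tumour replicate 1 lay nearer to stalk than tumour replicate 2, with 577.3 against 339.1 for RCA and 239.2 against 64 for HPR. The median of the photosystem list, -1.29, was -1.73 without tumour replicate 1 and -0.90 without tumour replicate 2. Adjusted over the list alone, all 7 and all 5 members fell. Without either stalk array 1 photosystem gene was called, without tumour replicate 2 3 were, and without wounded stalk replicate 2 2 genes of the Calvin cycle list were. Both lists passed camera as lower (adjusted p = 0.000752 each), but not with an estimated correlation (adjusted p = 0.325 each) or in fry (adjusted p = 0.0735 each). Leaving out either stalk array ended the calls of PSAE-1, ATPC1, HPR and PRK (adjusted p between 0.0517 and 0.0995), and for ATPC1 so did leaving out tumour replicate 2 (adjusted p = 0.0515).

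Among the added lists, 31 of 46 tested photosynthesis genes encoded in the chloroplast fell and 0 rose, with a median log2 change of -1.11. Without wounded stalk replicate 1, 8 fell, and without wounded stalk replicate 2, 4. The photosystem II genes psbC (ArthCp018), psbA (ArthCp002) and psbZ (ArthCp019) fell most, with changes of -2.37 ± 0.21, -2.15 ± 0.18 and -1.80 ± 0.16 (adjusted p = 0.00295, 0.00256 and 0.00301). The list passed camera as lower (adjusted p = 1.12e-12) and fry (adjusted p = 0.0459), but not camera with an estimated correlation (adjusted p = 0.64). Of 22 chloroplast genes for ribosomal proteins and RNA polymerase, 4 fell and 0 rose, and the list did not pass (adjusted p = 0.0691). Adjusted over the list alone, 0 of these fell, but the list did pass camera as lower without a filter (adjusted p = 0.0386). Limma called 0 of 10 tested genes encoded in the mitochondrion (0 at an unadjusted p under 0.05). Of 9 genes of chlorophyll and haem synthesis, 1 fell, LIL3:1 (AT4G17600), with a change of -1.90 ± 0.42 (adjusted p = 0.0248), a call that ended without either stalk array (adjusted p = 0.0937 and 0.137).

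Ribosomal proteins of the cytosol were higher in tumour. Of 105 tested, 81 rose and 1 fell, with a median log2 change of 0.87. Those risen numbered 8 without wounded stalk replicate 1, 14 without wounded stalk replicate 2 and 37 without tumour replicate 2. AT5G52650, AT3G14600 and AT5G22440 rose most, by 1.92 ± 0.23, 1.63 ± 0.18 and 1.61 ± 0.21 (adjusted p = 0.00524, 0.00443 and 0.00606). The 1 that fell was AT5G39850, with a change of -1.51 ± 0.33 (adjusted p = 0.0242), a call that ended without either stalk array (adjusted p = 0.113 and 0.122). This added list passed camera as higher (adjusted p = 1.44e-16) and fry (adjusted p = 0.0366), but not camera with an estimated correlation (adjusted p = 0.64).

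Cell division genes were higher too. In the fixed list of the cell cycle and DNA replication, all 3 tested members rose. They were PRL (AT4G02060), a subunit of the replicative MCM helicase (1.46 ± 0.26), and the Aurora kinases AUR1 (AT4G32830) (1.35 ± 0.22) and AUR2 (AT2G25880) (1.19 ± 0.22), with adjusted p = 0.0146, 0.0115 and 0.0152. In the added list of cell division, 10 of 17 rose and 1 fell. Those risen numbered 3 without wounded stalk replicate 1, 1 without wounded stalk replicate 2 and 6 without tumour replicate 2. The chromatin protein gene 3xHMG-box2 (AT4G23800) rose by 2.51 ± 0.43, the histone chaperone gene ASF1B (AT5G38110) by 1.90 ± 0.40 and POLA3 (AT5G41880), a primase subunit, by 1.74 ± 0.20. ATMAP65-6 (AT2G01910), a microtubule-associated protein, fell by 0.90 ± 0.19. The list passed camera as higher (adjusted p = 0.00501) and fry (adjusted p = 0.0372), but not camera with an estimated correlation (adjusted p = 0.64) or with the filter at the 60th percentile (median 0.32, adjusted p = 0.767). POLA3 kept its call without either stalk array, while PRL, AUR1, AUR2, ASF1B and ATMAP65-6 lost it without either (adjusted p between 0.0607 and 0.114). For AUR2 leaving out tumour replicate 1 also ended the call (adjusted p = 0.0561), for ASF1B and ATMAP65-6 leaving out tumour replicate 2 (adjusted p = 0.0584 and 0.0812), and for 3xHMG-box2 only leaving out wounded stalk replicate 2 (adjusted p = 0.0654). Limma called 0 of 5 histone genes (1 at an unadjusted p under 0.05), whose median was 0.31 and mean -0.04 (camera adjusted p = 0.943). Of 6 tubulin genes 1 rose, TUB5 (AT1G20010), by 2.07 ± 0.45, a call that ended without tumour replicate 1, wounded stalk replicate 1 or tumour replicate 2 (adjusted p = 0.0677, 0.0507 and 0.0584).

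The auxin list was higher in tumour. Of 6 tested members of the fixed auxin list, 2 rose and 0 fell. Besides GH3.3 this was IAA30 (AT3G62100), a member of the Aux/IAA family, with a change of 2.72 ± 0.33 (adjusted p = 0.00552). The 4 others had positive log2 changes of 0.45 to 2.06 that did not pass, and adjusted over the list alone 3 rose. Without tumour replicate 1, 4 rose. The median was 1.84, and 1.12 without tumour replicate 2. The list passed camera as higher (adjusted p = 0.0111), but not with an estimated correlation (adjusted p = 0.325) or in fry (adjusted p = 0.0735). The only tested member of the cytokinin list, the response regulator ARR15 (AT1G74890), rose by 1.46 ± 0.27 (adjusted p = 0.0157), and lost its call without either stalk array (adjusted p = 0.0731 and 0.0926). Among added genes, UGT76C2 (AT5G05860), which attaches glucose to cytokinins, rose by 3.25 ± 0.19, from 22.25 ± 0.212 in stalk to 290.2 ± 44.05 in tumour (adjusted p = 0.0014). Of the 16 tested UDP-glycosyltransferases as a whole, 4 rose and 5 fell. Leaving out each array in turn gave 2 to 5 risen and 1 to 4 fallen. Their median was positive (0.14) and the direction of camera was lower (adjusted p = 0.943).

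Sugar transporters of the SWEET family were lower in tumour. Of 6 tested, 4 fell and 0 rose. SWEET11 (AT3G48740), known for loading sucrose into the phloem, dropped from 698 ± 123 in stalk to 44.6 ± 3.89 in tumour, a log2 change of -3.71 ± 0.20 (adjusted p = 0.00118). SWEET1 (AT1G21460) and SWEET4 (AT3G28007) had changes of -2.15 ± 0.17 and -1.54 ± 0.18. This added list passed camera as lower (adjusted p = 0.00458) and fry (adjusted p = 0.0255), but not camera with an estimated correlation (adjusted p = 0.64) or without a filter on dim probe sets (median -0.08, adjusted p = 0.0569). In the fixed list of sucrose cleavage and sugar transport 1 of 2 tested members fell, the invertase gene AT1G62660, with a change of -1.29 ± 0.28 (adjusted p = 0.0233). In the fixed low-oxygen list, 2 of 3 rose. The transcription factor gene AT3G10040 rose by 3.70 ± 0.33 (adjusted p = 0.00299) and the lactate dehydrogenase gene AT4G17260 by 1.39 ± 0.30 (adjusted p = 0.023). PDC2 (AT5G54960), a pyruvate decarboxylase, had a change of -0.53 ± 0.17 that did not pass (adjusted p = 0.0641). Adjusted over the list alone, 2 rose and 1, PDC2, fell. AT1G62660 and AT4G17260 lost their calls without tumour replicate 1 or either stalk array (adjusted p between 0.0595 and 0.123). In the citrate cycle 6 of 13 rose and 0 fell, with cICDH (AT1G65930) at 1.37 ± 0.19 (not called without wounded stalk replicate 2, adjusted p = 0.0608), and the list did not pass camera (adjusted p = 0.0619), but did with quantile normalization (adjusted p = 0.0406) and without wounded stalk replicate 1 (adjusted p = 0.0403). Its risen genes numbered 1 without wounded stalk replicate 1, 0 without wounded stalk replicate 2 and 3 without tumour replicate 2.

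Class III peroxidases, enzymes of the cell wall and apoplast, were mostly higher in tumour. Of 21 tested, 12 rose and 1 fell. After AT4G36430 and Prx37, the next was AT5G06730, which rose by 3.85 ± 0.39 (adjusted p = 0.0037), and AT4G33420 fell by 3.03 ± 0.29 (adjusted p = 0.0033). The median was 1.44, but 0.31 without a filter on dim probe sets and 2.81 with the filter at the 60th percentile. This added list passed camera as higher (adjusted p = 0.00562) and fry (adjusted p = 0.0372), but not camera with an estimated correlation (adjusted p = 0.64). Single genes of other wall families rose or fell. XTH20 (AT5G48070), a xyloglucan endotransglucosylase, rose by 4.09 ± 0.24 (adjusted p = 0.00137), TBL39 (AT2G42570) and TBL36 (AT3G54260), of a family with roles in wall acetylation, by 4.05 ± 0.25 and 3.45 ± 0.45, and the endoglucanase gene GH9B13 (AT4G02290) by 2.66 ± 0.51. XTH32 (AT2G36870) and TBL38 (AT1G29050), of the same families, had changes of -1.73 ± 0.40 and -1.68 ± 0.32 (adjusted p = 0.0294 and 0.0166). XTH32 lost its call without either stalk array (adjusted p = 0.129 and 0.137) or a filter (adjusted p = 0.052), and TBL38 without wounded stalk replicate 1 or tumour replicate 2 (adjusted p = 0.0624 and 0.0563). In the fixed list of expansins and xyloglucan endotransglucosylases, 1 of 4 rose, XTH18 (AT4G30280), by 1.81 ± 0.38, a call that ended without tumour replicate 1 (adjusted p = 0.0644) or wounded stalk replicate 1 (adjusted p = 0.0854). Among lignin monomer genes CCR2 (AT1G80820) rose by 1.31 ± 0.26 and HCT (AT5G48930) was not called (adjusted p = 0.66), and CCR2 lost its call without either stalk array (adjusted p = 0.106 and 0.0909). Limma called neither tested gene of the secondary wall and xylem list, GUT2 (AT1G27440) or IRX15 (AT3G50220) (0 of 2, 0 at an unadjusted p under 0.05). The phloem regulator gene OPS (AT3G09070), the only tested member of the phloem list, rose by 2.58 ± 0.23 (adjusted p = 0.00308). Its stalk signals were 11.2 and 6.5, the second below the pseudocount.

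**Figure D2:**
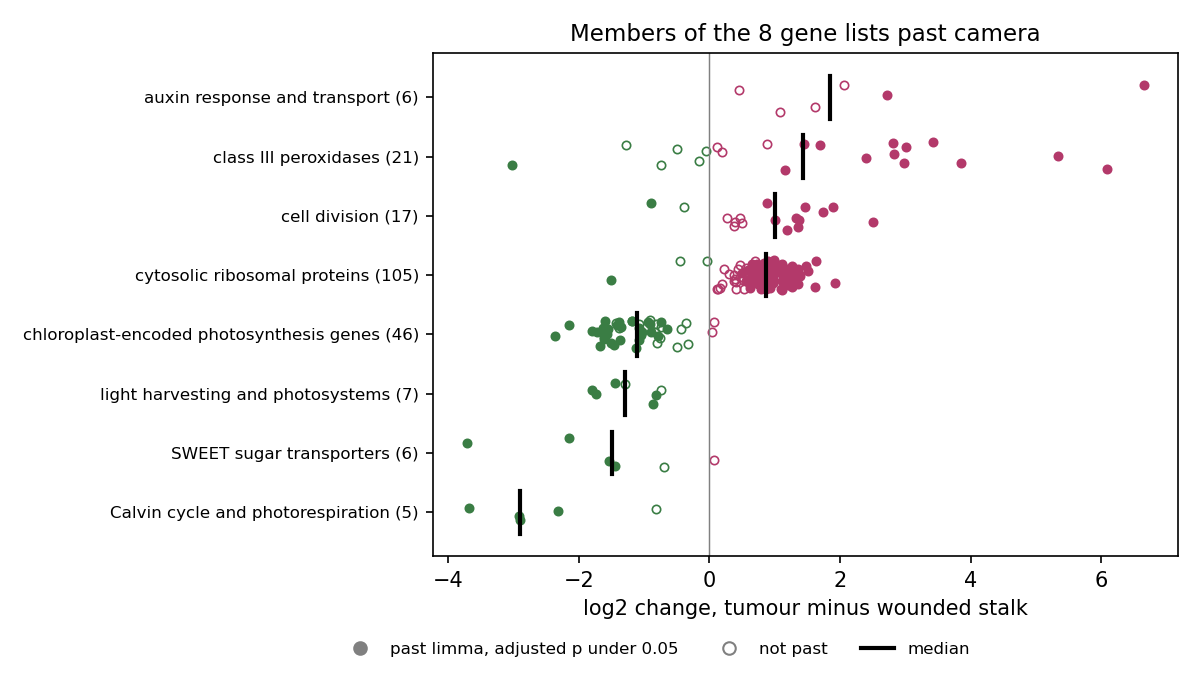
Log2 change in tumour against wounded stalk of the members of the 8 lists past camera, with the number tested in brackets, filled where a member passed limma and with the median as a bar. Medians run from -2.91 for the Calvin cycle and photorespiration to 1.84 for auxin.

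Defence and dehydration genes that were called in the fixed lists were lower in tumour. The defensin PDF1.2 (AT5G44420) read 9.75 ± 4.03 in tumour and 487 ± 362 in stalk, a log2 change of -4.52 ± 0.55 (adjusted p = 0.00546), while WRKY53 (AT4G23810), the other tested member of the salicylate and pathogen list, had a change of 0.02 (adjusted p = 0.957). The thionin THI2.1 (AT1G72260), the only tested member of the jasmonate and wounding list, fell by 1.75 ± 0.38 (adjusted p = 0.0243). COR15A (AT2G42540) and COR47 (AT1G20440), cold- and dehydration-induced proteins, had changes of -3.55 ± 0.54 and -2.05 ± 0.34 (adjusted p = 0.00929 and 0.0117), which is 2 of 3 tested members of the abscisate and dehydration list (3 of 3 adjusted over the list alone). COR15A and COR47 lost their calls without either stalk array (adjusted p between 0.057 and 0.0838), and THI2.1 without wounded stalk replicate 1 or tumour replicate 2 (adjusted p = 0.0763 and 0.0767). In the added list of dehydrins and LEA proteins 5 of 10 fell, AtLEA4-1 (AT1G32560) among them (-2.37 ± 0.24), and 3 rose, among them HVA22C (AT1G69700) (1.54 ± 0.19). Without either stalk array 2 fell and 1 rose, and without tumour replicate 2 6 fell and 1 rose. That list passed fry as lower (adjusted p = 0.0255) but not camera (adjusted p = 0.161, or 0.0462 without tumour replicate 2). Of 5 tested WRKY factors 2 rose, WRKY6 (AT1G62300) by 4.14 ± 0.22 and WRKY47 (AT4G01720) by 1.83 ± 0.22.

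No added list other than the 5 above passed camera (adjusted p between 0.059 and 0.943), and none passed it with an estimated correlation (adjusted p of 0.64 or more). Called members of all added lists, 148 risen and 73 fallen, numbered 42 and 22 without wounded stalk replicate 1, 46 and 21 without wounded stalk replicate 2 and 89 and 59 without tumour replicate 2. Among 7 glutathione transferases 4 fell and 0 rose, and among 5 cytochromes P450 of family 71B 3 fell and 0 rose. Both passed fry as lower (adjusted p = 0.0255 each). The glutathione transferases passed camera with the filter at the 60th percentile (adjusted p = 0.0169) and without tumour replicate 1, wounded stalk replicate 1 or tumour replicate 2 (adjusted p = 0.0343, 0.0412 and 0.0254), and family 71B without tumour replicate 2 (adjusted p = 0.0379). Without either stalk array 2 genes fell in each of these families. Among 10 beta-glucosidases 4 rose and 1 fell, and among 14 serine carboxypeptidase-like genes 3 rose and 3 fell. Leaving out each array in turn gave 1 to 4 risen beta-glucosidases, and 3 risen and 1 fallen carboxypeptidase-like genes. Both passed fry as higher (adjusted p = 0.0366 and 0.0372), as did the citrate cycle (adjusted p = 0.0459). In the wall lists, 2 of 7 expansins rose and 0 fell (0 called without wounded stalk replicate 2), 2 of 5 xyloglucan endotransglucosylases rose and 1 fell, 3 of 6 endoglucanases rose and 0 fell, and 3 of 12 TBL genes rose and 1 fell. Without wounded stalk replicate 1 the endoglucanases and the tubulins passed camera as higher (adjusted p = 0.0412 and 0.0388), while camera for the endoglucanases gave an adjusted p of 0.492 without tumour replicate 1. Only 1 endoglucanase rose without tumour replicate 1 or wounded stalk replicate 2. Of 10 genes of branched-chain amino acid breakdown 3 rose and 0 fell, and of 10 autophagy genes 2 rose and 1 fell. Without wounded stalk replicate 1, 0 were called in these lists and among the tetraspanins and RALF-like peptides, and 0 autophagy genes also without wounded stalk replicate 2 or tumour replicate 2. Without tumour replicate 1, 6 genes of branched-chain amino acid breakdown rose, and without tumour replicate 2, 1 of them and 4 RALF-like peptides. Of 7 tetraspanins 2 rose and 1 fell, of 8 RALF-like peptides 1 rose and 1 fell, and of 6 PUB ubiquitin ligases 1 rose and 1 fell. Of 14 genes of endoplasmic reticulum stress 1 fell and 0 rose, but 0 fell adjusted over the list alone or without any 1 of the arrays. The lists of 4 calmodulin-like genes (2 rose, 0 fell) and 3 vacuolar processing enzymes (1 rose, 1 fell) were too small to test.

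Of 50 landmark genes, 6 had a named probe set. Besides GH3.3, PYK10, RCA and PRK, these were the flavonoid gene DFR (AT5G42800), with a change of -1.43 ± 1.17 (adjusted p = 0.392, or 0.0256 with the replicate number as a block), and the reference gene PEX4 (AT5G25760), with a change of -0.13 ± 0.22 (adjusted p = 0.679). The sign of DFR turned without wounded stalk replicate 1 (0.10), and that of PEX4 without tumour replicate 1 or wounded stalk replicate 2 (0.03 each). Limma called 0 of 3 tested reference genes (0 at an unadjusted p under 0.05), and their log2 changes lay between -0.13 and 0.04. No fixed list for ethylene, suberin, epidermis, aquaporins, nitrogen, redox enzymes, floral organs or meristem had a tested member (0 each), so these 8 lists were not analysed here. PYK10 was the only tested member of the root list. Across all fixed lists, 12 of 47 tested entries rose, 14 fell and 21 were not called. In the fixed lists whose count adjusted over the list alone is not given above, it was the same.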

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

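All tests in this part were chosen after the values had been seen. A control probe set gave a signal on 1 array that no comparison above used. Among the 64 control probe sets, it alone had a tumour signal at least 10 times that of both stalk arrays and above the array median. It read 1680.3 on tumour replicate 1, 4.9 on tumour replicate 2, and 13.4 and 12.9 on the stalk arrays. A high background on that array is argued against, because the 27 control probe sets for 5 bacterial genes read at most 18.9 there, below the array median. A plant transcript shared by the tumours is argued against by the 4.9 on tumour replicate 2, below both stalk arrays. The tables used here identify it only by a probe set name with a sequence accession, and its target was not looked up.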

How the results depend on the processing

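The added lists were chosen after the annotation had been seen, and the alternatives before. No called probe set that was tested again changed sign under any refitted alternative (0 each). Both tumour arrays lay on the same side of both stalk arrays for every called probe set. Only quantile normalization and equal medians could therefore have turned a sign. Of the 125 called named genes, 64 kept their call under all alternatives that tested them. Counts of called probe sets moved by over 1.5 times under a threshold of 0.01 (732 higher, 780 lower) and with at least 2-fold change (1391 higher). Leaving out each array in turn gave 652 to 1701 higher and 659 to 1820 lower. Under these, calls of named genes were lost for 16 without tumour replicate 1, 24 without tumour replicate 2, 56 without wounded stalk replicate 1 and 52 without wounded stalk replicate 2, where fewer arrays carry the test. Without a filter 17 were lost. With 1 probe set per gene, 2147 were higher and 2005 lower; that alternative was not run for lists, which already take 1 probe set per gene.

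Fixed lists past the test numbered 1 higher and 2 lower. They fell to 0 and 0 with an estimated correlation (0 at an unadjusted p under 0.05), to 0 and 0 with fry, and the higher list to 0 with the 60th percentile filter, where it had too few members. Added lists numbered 3 higher and 2 lower. They were 0 and 0 with an estimated correlation (0 unadjusted) and 6 and 5 with fry; leaving out each array gave 3 to 6 higher and 2 to 6 lower. The cause was not tested, but in simulated data a list changed in truth was also lost with an estimated correlation (adjusted p = 0.534). Probe sets varied independently in that simulation. In the data, the estimated correlation was 0.608 to 0.75 for the fixed lists past camera and 0.0988 to 0.215 for the added ones. The preset was 0.01. Camera p also rose where the estimated correlation lay below that preset. For the glutathione transferases (-0.118) it went from 0.0122 to 0.123 unadjusted. For the methionine-derived glucosinolates of the closing part (-0.0225) it went from 3.18e-06 to 0.0412. Genes varying together above the preset are therefore argued against as the whole cause of the loss. For the lists with a higher estimate, the simulation does not settle which setting holds.

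Replicate numbers are shared between tissues, but no label says that they pair samples. Same-numbered arrays deviated together with r = 0.12 across probe sets. With the replicate number as a block, 2046 were higher and 2016 lower, with 1 and 2 fixed lists and 3 and 2 added lists. Dim probe sets are limited by background: between 18.7% and 22.2% of values per array lay under the pseudocount.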

Other observations

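The lists and tests in this part were chosen after the largest changes had been seen. Only the comparison of excess signal in stalk-rich probe sets was set out before its value was known. The genes named here were chosen after their values were seen. Heat-shock genes were lower in tumour than in wounded stalk. Of 17 tested, 12 fell and 0 rose, with a median log2 change of -3.49, or -2.14 without tumour replicate 2, and 7 fell without either stalk array. The small heat-shock protein genes AT1G54050 and AT5G37670 had changes of -4.6 ± 0.52 and -4.47 ± 0.33 (SE; limma adjusted p = 0.00457 and 0.00208). AT5G48570 read 2935 ± 531 in stalk and 212 ± 277 in tumour (mean ± SD, n = 2 each), a change of -4.85 ± 1.27 (limma adjusted p = 0.04) that was -2.81 without tumour replicate 2. Its call was lost without either stalk array (adjusted p = 0.169 and 0.153), without a pseudocount (adjusted p = 0.053) and without a filter (adjusted p = 0.0716). The list passed camera (adjusted p = 1.57e-07) and fry (adjusted p = 0.0382), but not camera with an estimated correlation (adjusted p = 0.228). Of the 12 members not seen before the list was written, 7 fell and 0 rose, with a median of -2.92 (camera adjusted p = 3.95e-05, estimated correlation adjusted p = 0.247).

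Genes for glucosinolates made from methionine, or for their transport, were lower in tumour. All 6 tested fell, with a median log2 change of -3.62. After BCAT4 and GSTU20, the glucosyltransferase gene AT2G31790 had a change of -3.72 ± 0.35, and the transporter genes GTR2 (AT5G62680) and GTR1 (AT3G47960) had changes of -3.53 ± 0.34 and -2.51 ± 0.25. The list passed camera (adjusted p = 3.18e-06) and fry (adjusted p = 0.00216), but not camera with an estimated correlation (adjusted p = 0.0955). The 3 members not seen before all fell and were too few to test.

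For heat-shock genes, tumour replicate 1 lay between tumour replicate 2 and the stalks: all 16 with a negative change read higher in it than in tumour replicate 2, by a median of 9.93% of the stalk signal (quartiles 7.9% and 20.6%). The comparison set out in advance decided nothing. In it, 96 other probe sets were at least 8-fold lower in tumour, with a stalk signal of 500 or more. They exceeded tumour replicate 2 by a median of 3.62% (quartiles 0.574% and 7.12%, 78 higher), and the upper quartile missed the bound set for it. Their choice by a mean over both tumour arrays limits that excess. Of 146 chosen later by the stalk signal and tumour replicate 2 alone, 129 read higher on tumour replicate 1. The median excess of the 146 was 6.57% (quartiles 2.18% and 11.6%). Choice by a low signal on tumour replicate 2 favours an excess, so neither set decides. The correlations of tumour replicate 1 with the stalks (0.678 and 0.665, against 0.59) also leave room for stalk tissue, but whole stalk tissue as the source of all of the heat-shock signal is argued against: 18 of the 96, and 18 of 146 chosen by the stalk signal and tumour replicate 2 alone, read under 2.48% of their stalk level on that array, a limit set after the quartiles had been seen. A common scaling error would move all probe sets alike and so cannot move 1 list alone. The median log2 change of all tested probe sets was 0.0677. The 18 probe sets for controls of the kind spiked in at hybridisation changed by -0.133 (log2, tumour minus stalk, -0.366 to 0.101 between single arrays), far less than the list. A smaller share, a part of the stalk, the tissue itself and conditions at harvest stay open.

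A hypothesis from the largest increases is that tumour tissue was low in oxygen. AT4G10270, AT4G33560 and AT5G10040 are among 19 tested genes recalled as a core response to low oxygen, of which 13 rose and 0 fell, with a median log2 change of 1.81. Adjusted over the list alone 13 rose and 1, PDC2, fell. The list passed camera (adjusted p = 2.6e-07) and fry (adjusted p = 0.00218), but not camera with an estimated correlation (adjusted p = 0.0955). Of the 11 members not seen before, 6 rose and 0 fell, with a median of 1.18. They passed camera (adjusted p = 0.000622) and fry (adjusted p = 0.00452) but not camera with an estimated correlation (p = 0.0696, adjusted p = 0.139). That failure decides nothing, because the estimated correlation of these members was -0.0309, below the preset of 0.01. A simulated list changed in truth failed the same test. The hypothesis stays open, as it rests on transcripts of a list recalled after the largest changes had been seen. A common scaling error could not have raised this list alone either (median of all tested probe sets 0.0677, spiked controls -0.133).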
